A study of Bos taurus with 72 samples.

How the data were processed

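Gene expression was measured in liver and placenta of 18 bovine fetuses on 72 oligonucleotide arrays. Per the labels, the fetuses were produced in vivo or in vitro and collected at gestation day 90 or 180, with 4 in vivo and 5 in vitro fetuses per day. Total RNA from the dissected tissues was reverse transcribed with random hexamers and aminoallyl-dUTP. Each array carried a tissue sample in Cy5 beside a common reference in Cy3, a pool of control fetal liver, placenta and kidney RNA. Dyes were not swapped. Each tissue of each fetus was hybridised on 2 arrays.

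The deposited values were a linear ratio of both channels for each of 27648 spots. Scanner, background correction, dye normalization, scaling between arrays and spot filters were not given in the sources used here, and neither was the numerator of the ratio. The deposited array medians ranged from 1.01 to 1.10 in in vivo day 90 liver, from 0.970 to 1.11 in in vitro day 90 liver, from 0.946 to 1.09 in in vivo day 180 liver and from 0.865 to 1.05 in in vitro day 180 liver. In placenta they ranged from 0.622 to 1.03 (in vivo, day 90), from 0.764 to 1.17 (in vitro, day 90), from 0.800 to 1.22 (in vivo, day 180) and from 0.897 to 1.13 (in vitro, day 180). Signal intensities were not part of the deposited values, so the signal over background behind each value is unknown, and the number of arrays limits the precision.

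The direction of the ratio was set from tissue markers. The deposited ratio of ALB, the liver's albumin, had a median of 1.01 over 36 liver arrays and 135 over 36 placenta arrays, and that of AFP 0.994 and 153. The placental lactogen gene CSH2 had medians of 121 in liver and 0.631 in placenta, and PAG2, a trophoblast glycoprotein gene, 51.4 and 0.723. The kidney transporters SLC12A3 (12.2 in liver, 11.7 in placenta) and SLC34A1 (8.61 and 11.7) were above 1 on all arrays of both tissues, with lowest values of 4.36 and 1.80. These values place the reference in the numerator, so the negative log2 of each deposited ratio was used as log2(tissue/reference). Every array was tested in the same way: hepatocyte minus trophoblast gene means lay between 4.12 and 5.75 in the liver arrays and between -6.61 and -4.23 in the placenta arrays. The sign of the tissue contrast therefore was an input and is no finding.

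Adjacent spots carried the same probe. Of 13824 such pairs, 8750 had an accession in common in the platform annotation and the others had none, and the correlation of the paired spots was 0.859 to 0.963 per array. Both spots of a pair were averaged on the log2 scale, after 4 values of 0 had been set to missing. By the platform annotation, which can be old, 17290 spots had 1 gene symbol, 210 had several and 10148 had none. Of the named spots, 17240 had a gene identifier in the RefSeq table of the current cattle assembly, which changed 0 symbols. Probes with several symbols were left unnamed. Probes of the same gene were averaged for the 518 genes with more than 1 probe. Only TMCC3 had probes that passed the liver gestation test in opposite directions (-0.81 and 0.58). This left 13238 features, 8073 named and 5165 unnamed, all of which had values for at least 3 fetuses in each group. No genome build was used, so no positions are given.

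The 2 arrays of a fetus and tissue were averaged and counted as 1 sample. Their median correlation was 0.873 (0.804 to 0.926) in liver and 0.912 (0.838 to 0.935) in placenta, against 0.784 and 0.792 for different fetuses of a group. For each tissue, limma (3.58.1 in R 4.3.3) fitted 4 group means to the 18 fetuses. Contrasts were in vitro minus in vivo at each day and averaged over both days, the interaction of production with day, and day 180 minus day 90 averaged over both productions. For comparisons between tissues, the placenta minus liver difference of each fetus was fitted in the same way, with fetus as the block. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences are given with their standard error (SE). The block by fetus rests on the shared animal name of the 2 tissue samples. Group-centred profiles of the liver and placenta of the same fetus had a median correlation of -0.0364 (-0.266 to 0.164, 18 pairs), and 0 of 18 livers correlated best with the placenta of the same fetus, so the values neither bear out nor contradict the pairing.

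Gene lists comprised 34 sets: hepatocyte secreted proteins, coagulation and complement, gluconeogenesis and glycogen, glycolysis, fatty acid oxidation and ketogenesis, fatty acid and triglyceride synthesis, cholesterol synthesis, urea cycle and amino acid breakdown, drug and bile acid metabolism, imprinted genes, DNA methylation and chromatin, IGF and insulin axis, trophoblast hormones and proteases, trophoblast transcription factors and epithelium, placental nutrient transport, angiogenesis and hypoxia, extracellular matrix, antioxidant defence, heat shock and ER stress, apoptosis and p53, cell cycle, oxidative phosphorylation, ribosomal proteins, interferon response and antigen presentation. They also held markers of erythroid cells, myeloid cells and macrophages, lymphoid cells, megakaryocytes and platelets, endothelial cells, stromal and stellate cells, cholangiocytes, endometrium, muscle and kidney. Of 1361 list entries, 834 were measured by symbol and 32 by a synonym. A transcript score, the mean of 67 short minus that of 46 long transcripts outside these lists, was computed per fetus. It may follow RNA quality, but no measure of RNA integrity was available to test this. Lists were tested with limma's camera, which compares a list with the other genes, at a preset correlation of 0.01, adjusted over the 34 lists of a contrast. Camera with an estimated correlation, and fry, which tests whether a list's genes move on balance in a single direction and compares them with no other genes, were alternatives.

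Contrasts, lists, thresholds, the rule for named genes and most alternatives were chosen before the data were examined. Up to 12 genes that rose and 12 that fell were named per contrast, those with the largest change among genes with an adjusted p under 0.05. Where fewer than 10 genes passed, the 5 with the smallest p in each direction were given as values. For each list described, up to 4 members with the smallest p were given. Imprinted, growth factor, methylation and tissue marker genes named in advance were given in the production contrasts. Of these, PEG10, MEG3, CDKN1C, ASCL2, DNMT3B, GHR, CSH1, PAG1 and FGB were not measured under those symbols. Chosen after the counts per tissue had been seen were the day by tissue interaction, the score of short minus long transcripts, arrays scaled to the same spread, array weights, tests on named features alone and list tests without each fetus.

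Alternatives were median-centred and quantile-normalised arrays, unaveraged probes, features measured on all arrays, robust moderation, only the first or second array, an array-level fit with fetus as random block and array number as replicate block, fits of only the groups compared, no term for gestation day, unpaired fits and leaving out each fetus. Fits were tested on simulated data made by adding known changes to 50 genes at each size of change. The simulated noise was drawn independently for each gene. Changes of all sizes were added to the same data, and the adjusted threshold is less strict where many genes change. Recovery would be lower where only few genes change. For the day-averaged production contrasts, a log2 change of 0.5 was recovered for 24% of genes in liver and 30% in placenta, and a change of 1 for 80% and 84%. At a single day, a change of 1 was recovered for 50% to 62%. A simulated shift of 1 list was called, with 0 other lists. Since the simulated genes were not correlated, these figures do not show how correlation between genes affects recovery or list calls here.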

Results

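Liver and placenta of cattle fetuses conceived in vivo or produced in vitro were profiled, and the question of the series is how the method of production changes gene expression in both tissues. Gestation day and tissue were the other factors. The 8 groups held 4 fetuses each for in vivo production and 5 each for in vitro production, at day 90 and day 180, and in liver and placenta. Of 13238 features, 8073 had a gene name. Values are log2(tissue/reference), and the median absolute deviation of a fetus's values ranged from 0.69 to 1.13 in liver and from 0.55 to 0.85 in placenta. The placenta of in vivo day 90 fetus 1 stood apart. Its median was 0.46 against -0.05 to 0.13 in the other 17 placentas, its trophoblast hormone list mean was -1.36 against -0.14 to 0.33, and its score of short minus long transcripts was -0.95 against -0.29 to 0.75.

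Placenta and liver were compared within each fetus to describe both tissues on this array. Placenta was higher in pregnancy-associated glycoproteins, which trophoblast secretes, in PRP4, a prolactin-related hormone, and in CSH2, placental lactogen. PAG4 differed by 8.10 on the log2 scale (SE 0.20), PAG5 by 7.57 (SE 0.18), PRP4 by 7.47 (SE 0.18) and CSH2 by 7.06 (SE 0.26). Of 26 measured trophoblast hormone and protease genes, 21 were higher and 2 lower (IFNT2 and HSD17B1), with the same counts adjusted over the list alone and a median of 5.87. Liver was higher in plasma proteins: AHSG, the fetal carrier protein fetuin, differed by -9.42 (SE 0.13), fibrinogen gamma FGG by -8.97 and the iron carrier TF by -7.94. All 27 hepatocyte secreted protein genes were lower in placenta (27 adjusted over the list alone), with a median of -6.89, as were 20 of 22 coagulation and complement genes, with C2 higher.

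Among the other genes with the largest differences, placenta was higher in PAG18, PAG14, PAG9, PAG8, the gap junction gene GJB2, PLET1, the WNT antagonist DKK1 and the galectin LGALS3, by 6.68 to 7.12. It was lower in the fatty acid binding protein FABP1, AMBP, the angiotensin precursor AGT, CHIA, the apolipoproteins APOH and APOC3, RGN, KNG1 and ORM1, by -9.07 to -7.45. All 24 genes kept their direction in 18 of 18 fetuses, which their choice as the largest differences made likely. In all, 8337 features differed by limma's test, 4249 higher and 4088 lower in placenta, and 2661 differed more than 2-fold. Since the ratio's direction came from such genes, their sign is no finding.

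Trophoblast transcription factors and epithelial genes were mostly higher in placenta (15 of 20, with 3 lower; 16 and 3 adjusted over the list alone), among them GATA3 (4.26) and HAND1 (4.12). Erythroid genes were lower in 13 of 15, among them ALAS2, the first enzyme of heme synthesis in red cells (-6.93), and 1 was higher, fetal liver being a site of blood formation. Urea cycle and amino acid breakdown genes were lower in 15 of 23 and higher in 4, among them OTC (-6.32) and CPS1 (-6.12). Of 6 cholangiocyte markers, 5 were higher, among them EPCAM (3.60) and MUC1 (4.42), which trophoblast epithelium also expresses. Counts adjusted over the list alone were the same for these lists, apart from the trophoblast transcription factors. Camera called 17 lists, and 7 kept their call with an estimated correlation: hepatocyte secreted proteins, coagulation and complement, urea cycle, trophoblast hormones, trophoblast transcription factors, erythroid cells and cholangiocytes (adjusted p = 0.00187 to 0.0389). The other 10 were glycolysis, extracellular matrix, stromal cells and endometrium, all higher, and fatty acid oxidation, cholesterol synthesis, drug and bile acid metabolism, imprinted genes, ribosomal proteins and megakaryocytes, all lower. Their adjusted p was 0.0852 to 0.546 with an estimated correlation. Of 28 measured imprinted genes, 17 were lower and 5 higher in placenta (17 and 5 adjusted over the list alone), among them NNAT (-7.02) and PLAGL1 (-4.14). Cholesterol synthesis was not called without any of 7 fetuses in turn (in vivo day 90 fetus 1, in vitro day 90 fetus 4, in vivo day 180 fetuses 1 to 3 and in vitro day 180 fetuses 3 and 5; adjusted p 0.0512 to 0.0821), nor stromal cells without in vivo day 90 fetus 1 (0.0514) or in vitro day 90 fetus 5 (0.0534).

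The production method was compared first in liver. IGF2 and H19, the imprinted growth factor gene and its neighbouring noncoding RNA, differed between in vitro and in vivo livers by 0.02 (95% interval -0.26 to 0.31) and -0.17 (-0.62 to 0.27), days averaged. IGF2R, the imprinted receptor that clears IGF2, differed by -0.40 (-0.86 to 0.06), and by -0.70 at day 180 (-1.35 to -0.05). IGFBP3, a carrier of insulin-like growth factors, differed by 0.45 (0.06 to 0.84), and by 0.71 at day 90 (0.15 to 1.26). None of the genes named in advance passed the adjusted threshold. The adjusted p of IGFBP3 was near 1, days averaged, and those of IGFBP3 at day 90 and IGF2R at day 180 were 0.999 and 0.992.

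By limma, 0 features changed between in vitro and in vivo liver with days averaged, 0 at day 90 and 0 at day 180, against 384, 299 and 386 at an unadjusted p under 0.05, where 662 were expected by chance. Livers of fetus 4 of every group, in vitro day 90 fetus 5 and in vitro day 180 fetus 2 had wide spreads (0.98 to 1.13). The other livers had 0.69 to 0.90. Trophoblast hormone list means were 0.29 to 0.48 in the wide livers and -0.39 to 0.15 in the others. The cause was not tested. Differences within groups widen the SE, so 0 features do not show that production had no effect. The genes with the smallest p, days averaged, were the adhesion gene CDH13 (0.55, SE 0.14), LOC512859 (0.75), the DNA repair gene XRCC2 (0.41), the phospholipase PLA2G1B (0.40) and the synaptic vesicle gene SYT1 (0.63) among higher values. The lower values were DZIP3 (-0.64), ECI2, an enzyme of fatty acid oxidation (-0.78), the calcineurin regulator RCAN1 (-0.60), DDO (-0.83) and the ammonium transporter RHBG (-0.73). At day 90 they were LOC512859 (1.15), XRCC2 (0.67), PTPA (1.08), GGT7 (0.91), ZNF211 (0.66), RCAN1 (-1.03), ECI2 (-1.23), EGLN3 (-0.76), MSMB (-1.61) and TAF9 (-0.93). At day 180 they were CDH13 (0.97), RAB3C (0.92), CHRNA3 (0.76), IL6 (0.92), MMP13 (0.94), RHBG (-1.35), DZIP3 (-0.93), GTPBP4 (-0.82), CUX2 (-1.02) and CMC4 (-0.71). The adjusted p of these genes was at least 0.956.

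Fatty acid and triglyceride synthesis genes as a list were lower in in vitro liver with days averaged (camera adjusted p 0.0014; adjusted p = 0.0482 with an estimated correlation). The desaturases FADS2 (-0.49, SE 0.17) and FADS1 (-0.45, SE 0.19) had the smallest p, 0 of 25 members passed by themselves (0 adjusted over the list alone), and 10 of 25 were above 0, with a median of -0.04. Coagulation and complement genes were lower as a list (adjusted p 0.00449; adjusted p = 0.135 with an estimated correlation), with a median of -0.04 and 0 of 22 members past the threshold (0 adjusted over the list alone). The complement gene C5 differed by -0.49 (SE 0.16) and F11 by -0.47. With median-centred, quantile-normalised and equally spread arrays, the coagulation median was -0.10, -0.09 and -0.08. That of fatty acid synthesis was -0.09, -0.06 and -0.04. Both calls held without any single fetus, but the fatty acid median ranged from -0.14 (without in vitro day 180 fetus 4) to -0.02 (in vitro day 90 fetus 3) and that of coagulation from -0.08 (in vitro day 90 fetus 1) to -0.01 (in vitro day 90 fetus 5). At day 180 the same lists were called with all fetuses in the fit (0.0461 for coagulation, 0.0184 for fatty acid synthesis; adjusted p = 0.400 and 0.164 with an estimated correlation). Coagulation lost this call without any of 7 fetuses in turn: in vivo day 90 fetus 4 (0.0585), in vitro day 90 fetus 4 (0.0512), in vivo day 180 fetuses 1 (0.560) and 4 (0.0836) and in vitro day 180 fetuses 2 (0.241), 3 (0.234) and 4 (0.0624). Fatty acid synthesis lost it without in vitro day 180 fetus 2 (0.115). Its day 180 median of -0.09 turned to 0.01 without in vivo day 180 fetus 3 (0.0441), and was -0.14 without in vivo day 180 fetus 1 or in vitro day 180 fetus 3 and -0.06 without in vitro day 180 fetus 5. At day 90 the cell cycle list was higher in in vitro liver, with a median of 0.21 and 39 of 46 genes above 0, none past the threshold over all genes or adjusted over the list alone (adjusted p 0.000545; adjusted p = 0.662 with an estimated correlation). It was not called without in vivo day 90 fetus 3 (0.0544, median 0.16) or in vitro day 90 fetus 4 (0.130, median 0.14). The production by day interaction changed 0 features by limma (321 at an unadjusted p under 0.05), and camera called the cell cycle list in it (median -0.24, adjusted p 0.00018; adjusted p = 0.723 with an estimated correlation). That call was lost without in vivo day 180 fetus 2 (0.0798, median -0.16), and the median was -0.38 without in vivo day 180 fetus 4 and -0.15 without in vitro day 180 fetus 2. The interaction's smallest p belonged to CSF1 (1.20), ELF3 (1.04), TBCB (1.06), TRHR (1.38), CYP1A2 (0.90), MYSM1 (-0.90), RAB4A (-0.79), RHBG (-1.23), PTPA (-1.15) and INPP5B (-0.88). Fry called 0 lists in these liver contrasts.

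In placenta, none of the genes named in advance passed the adjusted threshold between in vitro and in vivo production. With days averaged, IGF2 differed by -0.05 (95% interval -0.58 to 0.48), H19 by -0.22 (-0.70 to 0.26), the imprinted notch ligand DLK1 by -0.41 (-0.95 to 0.13) and PHLDA2, an imprinted gene that restrains placental growth, by -0.09. By limma 0 features changed, with 201 at an unadjusted p under 0.05. The genes with the smallest p were FSCN2 (0.64), PHOSPHO1 (0.82), CYP2E1 (0.37), ERP44 (0.47), MMP13 (0.46), the estrogen receptor ESR2 (-0.45), FOXP4 (-0.39), the WNT antagonist FRZB (-0.49), GNGT1 (-0.53) and SLC18A2 (-0.85), all with an adjusted p near 1. Camera called 6 lists as higher in in vitro placenta: glycolysis, trophoblast hormones, antioxidant defence, cell cycle, oxidative phosphorylation (median 0.11, 58 of 68 genes above 0, adjusted p 9.42e-11) and ribosomal proteins. Their adjusted p was 0.600 to 0.963 with an estimated correlation. Of these 6 calls, 0 remained without in vivo day 90 fetus 1, where the adjusted p of oxidative phosphorylation was 0.0814 and that of cell cycle 0.595. Glycolysis also lost its call without in vitro day 90 fetuses 3 and 4, in vivo day 180 fetus 3 and in vitro day 180 fetuses 1, 2 and 3 (0.0654 to 0.274), and antioxidant defence without in vitro day 90 fetus 5 and day 180 fetus 3 of either production (0.0615 to 0.122). Interferon response (0.0130) and myeloid cells (0.0371) were called as higher without in vivo day 90 fetus 1.

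**Figure D1:**
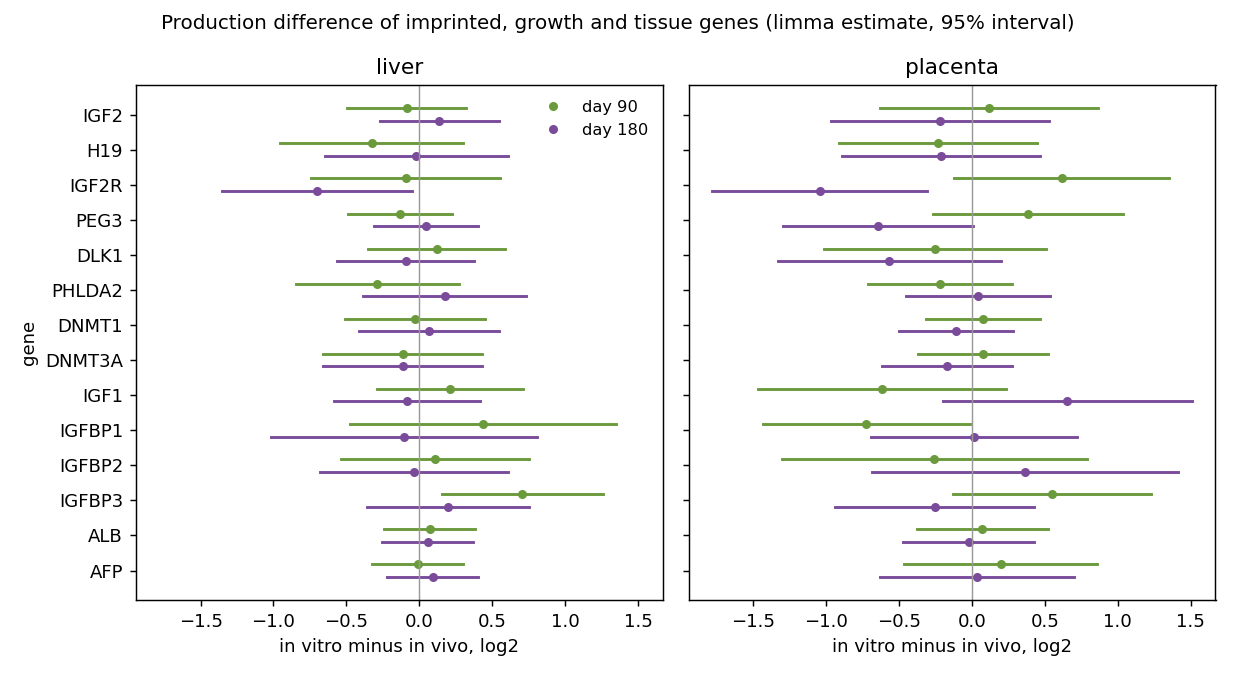
Log2 difference between in vitro and in vivo production for 14 imprinted, growth, methylation and plasma protein genes in liver and placenta, at day 90 (green) and day 180 (purple), with limma's 95% intervals (4 in vivo and 5 in vitro fetuses per day). No gene passed the adjusted threshold; IGF2R in placenta was 0.61 at day 90 and -1.04 at day 180.

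Extracellular matrix genes lay on opposite sides at both days in placenta with all fetuses in the fit. At day 90 their list median was 0.18 (camera adjusted p 0.00161; adjusted p = 0.826 with an estimated correlation), with the basement membrane collagen COL4A1 at 1.19 (SE 0.53) and COL12A1 at 0.94. At day 180 it was -0.28 (0.000189; adjusted p = 0.866 with an estimated correlation), with COL4A1 at -1.42 (SE 0.53), the laminin LAMB1 at -1.24 and fibronectin FN1 at -1.55. The interaction of production with day had a list median of -0.43 (4.7e-05; adjusted p = 0.868 with an estimated correlation). The score of short minus long transcripts moved with this list: with the score as covariate the interaction median was 0.07, so its direction turned. In these 3 contrasts 0 of 45 members passed, over all genes or adjusted over the list alone. Without in vivo day 90 fetus 1 the medians were 0.47 (5.05e-12), -0.28 (0.000115) and -0.86 (5.31e-09). The day 90 direction rested on other single fetuses too, since the median was -0.20 without in vivo day 90 fetus 3 (0.568, not called), -0.01 without in vivo day 90 fetus 4 (0.0417), 0.03 without in vitro day 90 fetus 5 (0.190, not called) and 0.06 without in vitro day 90 fetus 2 (0.00406). The interaction median was -0.02 (0.00411), -0.24 (0.000224) and -0.26 (0.00229) without the first 3 of these, and the day 180 median was -0.43 (1.77e-05) without in vivo day 180 fetus 4. IGF2R differed by 0.61 at day 90 and by -1.04 at day 180 (95% interval -1.78 to -0.31, adjusted p 0.598).

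Genes for ribosomes and for respiration were higher as lists in in vitro placenta at day 180, and endothelial genes lower, with adjusted p = 0.866 with an estimated correlation for each list. The score of short minus long transcripts moved with these lists, at 0.26 (SD 0.42, n = 5) in in vitro and -0.19 (SD 0.05, n = 4) in in vivo placenta at day 180. Ribosomal protein genes had a median of 0.30 with 42 of 55 above 0, among them RPS2 (0.82). Oxidative phosphorylation genes had a median of 0.18 with 52 of 68 above 0, among them NDUFV2 of respiratory complex I (0.65). Endothelial genes had a median of -0.36 with 2 of 17 above 0, among them PECAM1 (-0.82) and PLVAP (-0.76). Heat shock and endoplasmic reticulum stress genes, with the chaperone HSPA5 at -0.94, and cholesterol synthesis genes, with HSD17B7 at -0.92, were also called as lower. Camera's adjusted p was 4.89e-05 for ribosomal and respiratory genes, 0.00429 for endothelial, 0.0351 for heat shock and 0.0477 for cholesterol synthesis genes, and these too had an adjusted p = 0.866 with an estimated correlation. Cholesterol synthesis lost its call without any of 9 fetuses in turn (in vivo day 90 fetuses 1, 3 and 4, in vivo day 180 fetuses 1, 2 and 4 and in vitro day 180 fetuses 3, 4 and 5; 0.0547 to 0.190), and heat shock without any of 6 (in vivo day 90 fetus 1, in vivo day 180 fetuses 1, 2 and 4 and in vitro day 180 fetuses 4 and 5; 0.0579 to 0.215). Over all genes 0 members passed, and adjusted over the list alone 1 did in cholesterol synthesis and 0 in the others.

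At day 90, camera also called cholesterol synthesis (median 0.22), trophoblast hormones (0.18), heat shock and endoplasmic reticulum stress (0.20) and cell cycle genes (0.22) as higher in in vitro placenta, with HSD17B1 at 0.84, PDIA6 at 0.87 and CKS2 at 0.99. Their adjusted p was 3.41e-06 to 0.00424, and adjusted p = 0.816 with an estimated correlation. None of these 4 was called without in vivo day 90 fetus 1: cell cycle had an adjusted p of 0.286 and trophoblast hormones 0.924. Oxidative phosphorylation (0.0148) and ribosomal proteins (4.11e-07) were then called as lower, and interferon response (4.00e-05) and endothelial cells (0.000161) as higher. Without any other single fetus all 4 kept their call. The cholesterol synthesis median was 0.41 without in vivo day 90 fetus 2, 0.13 without in vivo day 90 fetus 3 and 0.12 without in vitro day 90 fetus 2. That of trophoblast hormones was 0.28 and 0.30 without in vivo day 90 fetuses 2 and 3, that of cell cycle 0.39, 0.33 and 0.34 without in vivo day 90 fetuses 2 and 4 and in vitro day 90 fetus 5, and that of heat shock 0.13 without in vitro day 90 fetus 1. In the interaction, heat shock, cholesterol synthesis, cell cycle and endothelial genes were lower (medians -0.34, -0.54, -0.16 and -0.35; adjusted p 0.00338, 0.00338, 0.0164 and 0.0164; adjusted p = 0.868 with an estimated correlation). Adjusted over the list alone, 1 heat shock gene rose and 5 fell, and 2 cholesterol synthesis genes fell. Without in vivo day 90 fetus 1, cholesterol synthesis (0.125, median -0.35) and cell cycle (0.480, median 0.16) lost their call there, the endothelial median was -0.61, and interferon response was called as lower (0.0125) and oxidative phosphorylation (7.42e-05) and ribosomal proteins (3.76e-07) as higher. Cell cycle also lost its call in the interaction without in vitro day 90 fetus 1 (0.0715, median -0.09) and in vivo day 180 fetus 1 (0.0664, median -0.13), as did endothelial genes without in vivo day 90 fetuses 3 (0.0703) and 4 (0.0687; median -0.20 for each). The cell cycle median there was -0.30, -0.29 and -0.26 without in vivo day 90 fetuses 2 and 4 and in vitro day 90 fetus 5, -0.07 without in vitro day 90 fetus 2 and -0.08 without in vitro day 180 fetus 2. With the transcript score as covariate, the endothelial median turned to 0.13, that of cell cycle was -0.44, and those of heat shock and cholesterol synthesis were -0.32 and -0.53. The median of all features in this contrast was 0.12, so these list values are relative to a shift of that size. The interaction median of cell cycle genes was -0.31 with median-centred arrays and -0.007 with arrays scaled to the same spread. That of heat shock genes was -0.49 and -0.21.

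Single genes in placenta did not pass at either day: by limma 0 features changed at day 90 and 0 at day 180, with 909 and 1029 at an unadjusted p under 0.05. In the interaction, 1 unnamed probe passed (adjusted p 0.0283), with 1883 at an unadjusted p under 0.05. The smallest p at day 90 belonged to MYADM (0.84), AFG3L2 (0.53), the cholesterol transporter NPC1 (1.14), CLDN7 (0.75), COL12A1 (0.94), DUSP22 (-0.85), FOXP4 (-0.71), ECHDC1 (-0.75), CPS1 (-0.95) and BEX4 (-1.07). At day 180 they belonged to C17H22orf39 (0.72), SLC25A6 (1.001), LSM1 (0.93), CYP2E1 (0.69), GLRX5 (1.10), HSD17B7 (-0.92), CHMP4B (-0.94), VOPP1 (-1.11), A2M (-1.46) and the gap junction gene GJA1 (-1.18). In the interaction they belonged to HEBP2 (1.98), ECHDC1 (1.27), UQCR11 (1.05), TTC32 (1.22), SLC25A6 (1.55), GJA1 (-2.08), MYADM (-1.49), MYO1D (-1.87), MCAM (-1.99) and NPC1 (-2.09), with adjusted p from 0.180. Leaving out in vivo day 90 fetus 2 gave 13 features at day 90 and 328 in the interaction, and without in vitro day 180 fetus 1 the interaction had 59. Without any of 11 of the 18 fetuses in turn the interaction had 0: in vivo day 90 fetuses 3 and 4, in vitro day 90 fetuses 1, 3 and 4, in vivo day 180 fetuses 1, 2 and 3 and in vitro day 180 fetuses 2, 3 and 4. It also had 0 with median centring, with quantile normalization, with only the first array and with only the second, so its single probe was not stable. With array weights, under which in vivo day 90 fetuses 1 and 4 had weights of 0.116 and 6.09, 1664 features changed at day 90, 57 at day 180 and 3220 in the interaction.

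Whether production differences varied between tissues was tested within fetuses. The desaturases FADS2 (0.83, SE 0.25) and FADS1 (0.72, SE 0.25), which make long polyunsaturated fatty acids, had the smallest p of their list. By camera, the production difference of fatty acid and triglyceride synthesis was higher in placenta than in liver (median 0.06, adjusted p 0.0135, adjusted p = 0.0966 with an estimated correlation). This median was 0.15 with median-centred arrays, 0.14 with quantile-normalised ones and 0.02 with arrays scaled to the same spread. Oxidative phosphorylation (median 0.12, 8.38e-08), ribosomal proteins (0.11, 0.000473) and glycolysis (0.11, 0.0490) were called in the same direction, with adjusted p = 0.471 to 0.635 with an estimated correlation. In these 4 lists 0 genes passed, over all genes or adjusted over the list alone. Without in vivo day 90 fetus 1, fatty acid synthesis (0.0208, median 0.13) and oxidative phosphorylation (0.0274, median 0.02) kept their call, and ribosomal proteins (0.860) and glycolysis (0.463) lost it. Glycolysis also lost its call without in vitro day 90 fetuses 1 and 3, in vivo day 180 fetuses 2 and 3 and in vitro day 180 fetuses 2 and 3 (0.0548 to 0.175), and fatty acid synthesis without in vitro day 90 fetus 5 (0.0909) and in vivo day 180 fetus 3 (0.0782). The fatty acid median turned to -0.01 without in vivo day 90 fetus 3 (0.0165). The respiratory median was 0.18 to 0.19 without in vivo day 90 fetus 4, in vitro day 90 fetus 5 or in vivo day 180 fetus 4, and the ribosomal 0.17 without in vivo day 90 fetus 3 and 0.06 without in vivo day 180 fetus 1 or in vitro day 180 fetus 3. With in vivo day 90 fetus 1 left out, cell cycle genes were called as lower (0.0208, median -0.12), and extracellular matrix, interferon response (0.0269 each), myeloid and endometrium genes (0.0208 each) as higher. By limma 0 features differed, with 327 at an unadjusted p under 0.05. The smallest p belonged to DDO (0.96), FADS2, ERP44 (0.71), RHBG (1.07), LOC785216 (0.69), ESR2 (-0.90), TCEAL9 (-0.80), TRPC6 (-0.76), SLC18A2 (-0.87) and TMEM237 (-0.63), with adjusted p near 1.

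Gestation day was compared next. Fetal liver at day 180 was lower in genes of cell division and of red cell formation than at day 90. Of 46 measured cell cycle genes, 32 fell and 0 rose (37 and 0 adjusted over the list alone), with a median of -0.73. The mitotic kinase CDK1 fell by 1.08 (SE 0.16), its cyclin CCNB2 by 0.89 and the kinetochore motor gene CENPE by 1.30. Of 15 erythroid genes 12 fell (12 adjusted over the list alone), among them ALAS2 (-1.38, SE 0.16, adjusted p 2.91e-05), AHSP, the chaperone of alpha globin (-1.31), and the heme synthesis enzymes CPOX (-1.07) and UROD (-0.71). Only the carbonic anhydrase CA2 rose (1.36). In each of 9 day 180 livers, the list means of both groups lay below those of all 9 day 90 livers (exact permutation p 4.11e-05 for each).

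Connective tissue genes rose in fetal liver over the same interval. Of 45 extracellular matrix genes 16 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 0.46, among them the collagen chains COL1A2 (1.72), COL1A1 (1.15) and COL6A3 (0.78) and the matrix protein SPARC (1.10). Of 14 markers of stromal and stellate cells 8 rose (9 adjusted over the list alone; median 0.66), among them the smooth muscle genes MYH11 (1.13) and TAGLN (0.90), and 4 of them, COL1A1, COL1A2, COL3A1 and DCN, also are on the matrix list. Complement and coagulation genes rose in 6 of 22 and fell in 0 (6 and 0 adjusted over the list alone; median 0.37). The complement proteases C1R and C1S rose 4.16-fold and 3.99-fold (2.06, SE 0.17, and 2.00, SE 0.18), and C3, the central complement protein, by 1.02.

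**Figure D2:**
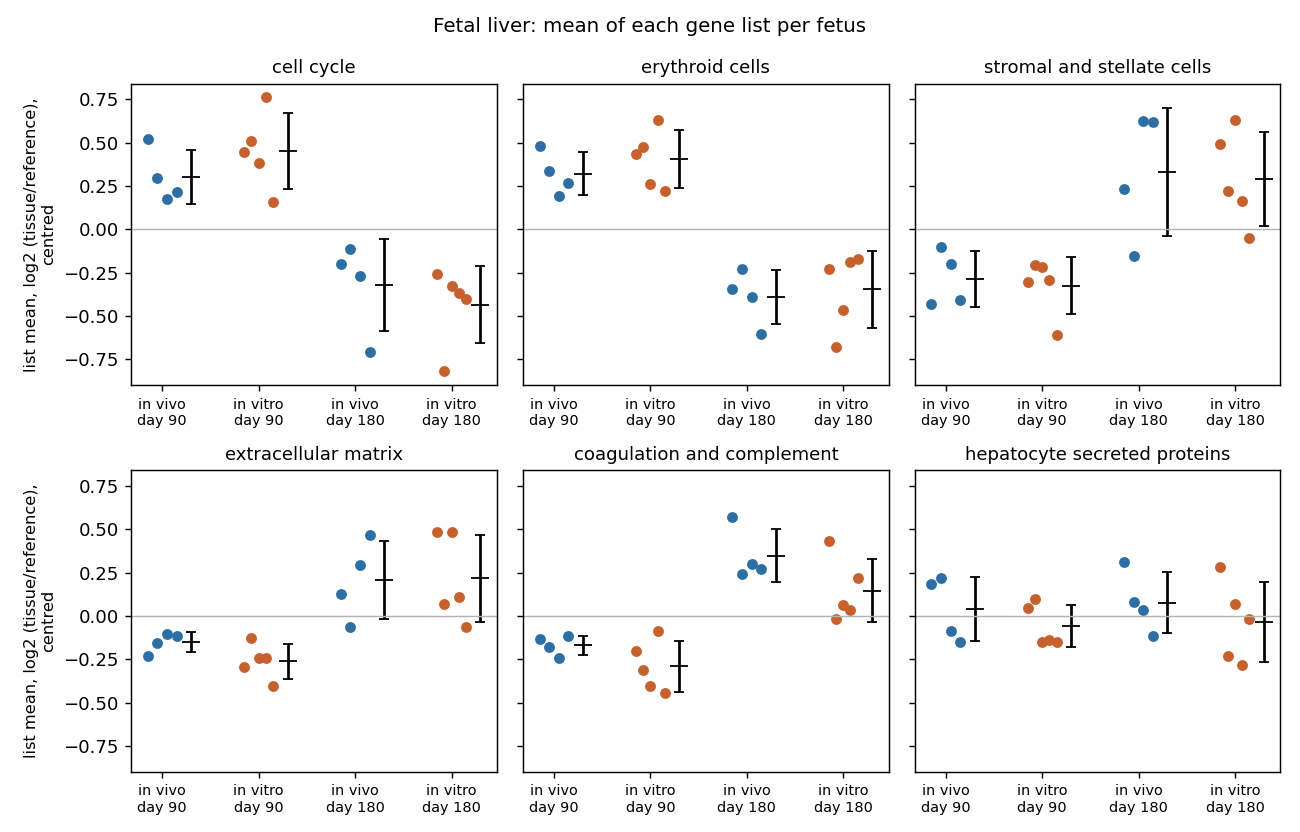
Mean log2(tissue/reference) of 6 gene lists in fetal liver, with each fetus centred on its own median and each gene on its mean over 18 fetuses. Points are fetuses, and bars are group means with SD (4 in vivo and 5 in vitro fetuses per day). Cell cycle and erythroid lists lie lower in all day 180 livers than in all day 90 livers, and the median change of extracellular matrix genes was 0.46.

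The growth factor gene IGF1 rose by 1.38 (SE 0.17, adjusted p 6.16e-05), and its binding proteins IGFBP2 (1.35), IGFBP3 (1.09), IGFBP4 (0.61) and IGFBP5 (0.56) rose with it. These were 5 of 26 measured genes of the IGF and insulin axis, with 0 lower (5 and 0 adjusted over the list alone). Immune genes rose too: 10 of 26 myeloid genes (10 adjusted over the list alone), among them the neutrophil genes CAMP (1.18) and S100A9 (1.26), 5 of 19 lymphoid genes (6 adjusted over the list alone, with 1 lower), among them CD3E of T cells (1.21), and 7 of 27 genes of interferon response and antigen presentation (9 adjusted over the list alone), among them CXCL10 (1.27) and BOLA-DRA (1.15). Genes of drug and bile acid metabolism rose in 5 of 27 (7 adjusted over the list alone), among them the bile acid importer SLC10A1 (1.10) and ADH4 (1.44). Transporters of the placental nutrient list fell in 7 of 31 and rose in 1 (7 and 2 adjusted over the list alone), among them the glucose transporter SLC2A1 (-1.14). With the score of short minus long transcripts as covariate, this list's median turned from -0.12 to 0.09 and camera no longer called it (adjusted p 0.263).

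Genes of respiration and translation fell by smaller amounts. A score of short minus long transcripts, which may follow RNA quality, was 0.12 at day 90 (SD 0.13, n = 9) and -0.12 at day 180 (SD 0.14, n = 9, exact permutation p 0.000905). It moved with this group and with the cell cycle and erythroid genes. Of 68 oxidative phosphorylation genes 14 fell, among them CYC1 of complex III (-0.77), and NDUFS7 rose (0.83; 25 and 1 adjusted over the list alone; median -0.33). Of 55 ribosomal protein genes 9 fell (12 adjusted over the list alone; median -0.35, and -0.22 with the score as covariate), among them RPL24 (-0.86). Of 34 DNA methylation and chromatin genes 5 fell (7 lower and 3 higher adjusted over the list alone), among them the histone methyltransferase EZH2 (-0.80) and HELLS (-0.71), and the maintenance methyltransferase DNMT1 differed by -0.46 (adjusted p 0.0692). Antioxidant defence genes fell in 7 of 31 and TXNIP rose (8 and 1 adjusted over the list alone), among them PRDX2 (-1.18), abundant in red cells, and FTH1 (-0.81). The mean of this list was -0.12 and its median 0.01, which was -0.06 with median-centred arrays and -0.12 with quantile-normalised ones. It was below 0 in 13 of 18 fits without 1 fetus, lowest without in vivo day 180 fetus 4 (-0.05), and the call held in all 18. The desaturases FADS1 (-1.12) and FADS2 (-0.74) fell with FABP3 among 25 fatty acid synthesis genes, and THRSP rose (7 and 2 adjusted over the list alone). In cholesterol synthesis SQLE fell (-0.74, 1 of 14, and 1 adjusted over the list alone), and in glycolysis LDHA (-0.79) and PGK1 (-0.47) did (2 of 18, and 2 adjusted over the list alone). With the score as covariate, the glycolysis median went from -0.15 to 0.01. Camera then no longer called glycolysis (adjusted p 0.490), cholesterol synthesis (0.117) or antioxidant defence (0.0785).

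Camera called all 18 lists named for the day contrast so far, 8 higher and 10 lower at day 180. With an estimated correlation 8 calls held, with adjusted p = 0.0140 to 0.0311: cell cycle, erythroid cells, DNA methylation and chromatin, coagulation and complement, oxidative phosphorylation, ribosomal proteins, stromal cells and extracellular matrix. The other calls were lost: adjusted p = 0.0841, 0.142 and 0.0766 with an estimated correlation for myeloid, lymphoid and interferon genes, 0.147 for the IGF axis, 0.270 for drug metabolism, 0.0701 for fatty acid synthesis and for nutrient transport, 0.102 for cholesterol synthesis and for glycolysis and 0.187 for antioxidant defence. Leaving out a fetus cost glycolysis its call for in vivo day 90 fetus 4 (0.0647), in vitro day 90 fetus 5 (0.0553) and day 180 fetus 3 of either production (0.0623 in vivo, 0.0744 in vitro), and cholesterol synthesis for day 180 fetus 4 of either production (0.05002 in vivo, 0.0549 in vitro). Fry called 19 lists. With the transcript score as covariate, camera at the preset correlation kept all of these calls except glycolysis, cholesterol synthesis, nutrient transport and antioxidant defence. With the score and an estimated correlation, myeloid (adjusted p 0.0134) and interferon genes (0.0355) were called, while matrix, stromal, respiratory and ribosomal genes were not.

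Lists that were not called by camera held single genes that passed. Hepatocyte secreted proteins rose in 4 of 27 and fell in 3 (6 and 3 adjusted over the list alone), among them TTR (0.70), a carrier of thyroid hormone, and ORM1 (-1.36). FBP1 (0.85) rose and PCK2 (-0.68) fell among 15 genes of gluconeogenesis and glycogen, the fatty acid sensor PPARA (0.51) rose among 21 of fatty acid oxidation, and GOT1 (-0.63) fell among 23 of urea cycle and amino acid breakdown. Imprinted genes changed in 3 of 28: PLAGL1 fell (-0.78), and SGCE (0.68) and DCN (0.52) rose. SULT1E1 rose among 26 trophoblast hormone and protease genes, FGFR2 (0.48) among 20 trophoblast transcription factor and epithelial genes, and 3 rose and 2 fell among 29 of angiogenesis and hypoxia, among them ADM (0.71) and THBS1 (-0.88). Heat shock genes rose in 4 of 28, among them DNAJB1 (0.98), and apoptosis genes rose in 1 and fell in 2 of 21, among them BCL2L1 (-0.97). The platelet gene PF4 fell (-1.05; 1 of 5), as did the endothelial genes CD34 (-0.67) and PLVAP (-0.47; 2 of 17), and the muscle genes MYH3 (0.67) and DES (0.55) rose (2 of 18). Of 6 cholangiocyte, 16 endometrium and 6 kidney markers 0 passed. Adjusted over the list alone, 2 genes rose and 1 fell in gluconeogenesis, 4 rose in fatty acid oxidation, 0 passed among trophoblast transcription factors, 5 rose and 2 fell in angiogenesis, 1 rose and 2 fell among endothelial genes, and the other lists of this group kept their counts.

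Of single genes, CXCL9, a chemokine that draws T cells, had the largest rise, 5.44-fold (2.44, SE 0.36, adjusted p 0.000291). Next were HSD17B6 (2.35), the prolactin receptor PRLR (2.07), the estrogen sulfotransferase SULT1E1 (2.06), the calcification inhibitor MGP (1.82), SPARCL1 (1.81), LOC508459 (1.74), PLN (1.72) and the chemokine CCL2 (1.61). The calcium-binding protein gene S100G fell most (-1.58, SE 0.22, adjusted p 0.000199), then the mitotic kinesin KIF15 (-1.50), NCAPG (-1.32), ODC1 of polyamine synthesis (-1.31), SSX5 and the histone gene H1-3 (-1.26 each) and CDCA2 (-1.18). All 24 genes named by rule were shifted in their direction from the day 90 mean in 9 of 9 day 180 fetuses, which their choice as the largest changes made likely. By limma 1551 features changed, 869 higher and 682 lower at day 180, and 147 of them more than 2-fold. With only the first array of each fetus 536 changed, with array weights 2437, and without in vivo day 90 fetus 1, 985. With the transcript length score as covariate 148 changed, 136 of them among the 1551. The share of higher features was 56.0% as deposited, 38.3% with median-centred and 40.9% with quantile-normalised arrays, and the list medians given here kept their sign under both, except that of antioxidant defence.

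In placenta, hormone genes of trophoblast were higher as a list at day 180 than at day 90, and connective tissue and immune genes lower. With an estimated correlation 0 of camera's 8 calls held, with adjusted p = 0.0834 with an estimated correlation for trophoblast hormones and 0.904 for the other 7 lists. Trophoblast hormone and protease genes had a median of 0.20 with 19 of 26 above 0, among them the aromatase gene CYP19A1 (1.68, SE 0.53) and HSD3B1 of progesterone synthesis (0.59). Stromal and stellate markers had a median of -0.27 with 0 of 14 above 0, and extracellular matrix genes one of -0.32 with 1 of 45 above 0, among them COL1A2 (-1.14) and COL3A1 (-0.98). Myeloid genes had a median of -0.32, among them the lipopolysaccharide receptor CD14 (-0.85), lymphoid genes one of -0.36 and interferon response genes one of -0.23. Trophoblast transcription factors (median 0.12) and heat shock genes (0.02) were called as higher, both with adjusted p = 0.904 with an estimated correlation. In these 8 lists 0 members passed over all genes, and adjusted over the list alone 1 passed in extracellular matrix, 1 in stromal cells and 0 in the others.

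Camera's adjusted p was 2.93e-09 for trophoblast hormones, 5.72e-07 for extracellular matrix, 2.78e-05 for stromal, 3.58e-05 for myeloid, 0.000252 for interferon response, 0.0224 for lymphoid, 0.00225 for trophoblast transcription factor and 0.0375 for heat shock genes. Without in vivo day 90 fetus 1, 4 calls remained: trophoblast hormones (0.00397, median 0.09), extracellular matrix (0.00509, median -0.14), myeloid (0.00397, median -0.23) and stromal genes (0.00915, median -0.15). Lymphoid, interferon response, heat shock and trophoblast transcription factor genes lost theirs (0.314, 0.103, 0.261 and 0.165), and cell cycle (0.00391), oxidative phosphorylation and ribosomal protein genes (5.00e-06 each) were then called as lower. Heat shock genes also lost their call without any of 8 other fetuses in turn (in vivo day 90 fetuses 3 and 4, in vitro day 90 fetuses 3 and 4, in vivo day 180 fetuses 1, 2 and 4 and in vitro day 180 fetus 1; 0.0520 to 0.613), and in 5 of these fits their median was below 0. Lymphoid genes lost theirs without in vitro day 90 fetus 5 (0.149), in vivo day 180 fetus 1 (0.101) and in vitro day 180 fetus 1 (0.202). The stromal median was -0.42 without in vivo day 90 fetus 2, and that of trophoblast transcription factors was 0.08 without in vivo day 90 fetus 3 and 0.18 without in vivo day 180 fetus 3.

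**Figure D3:**
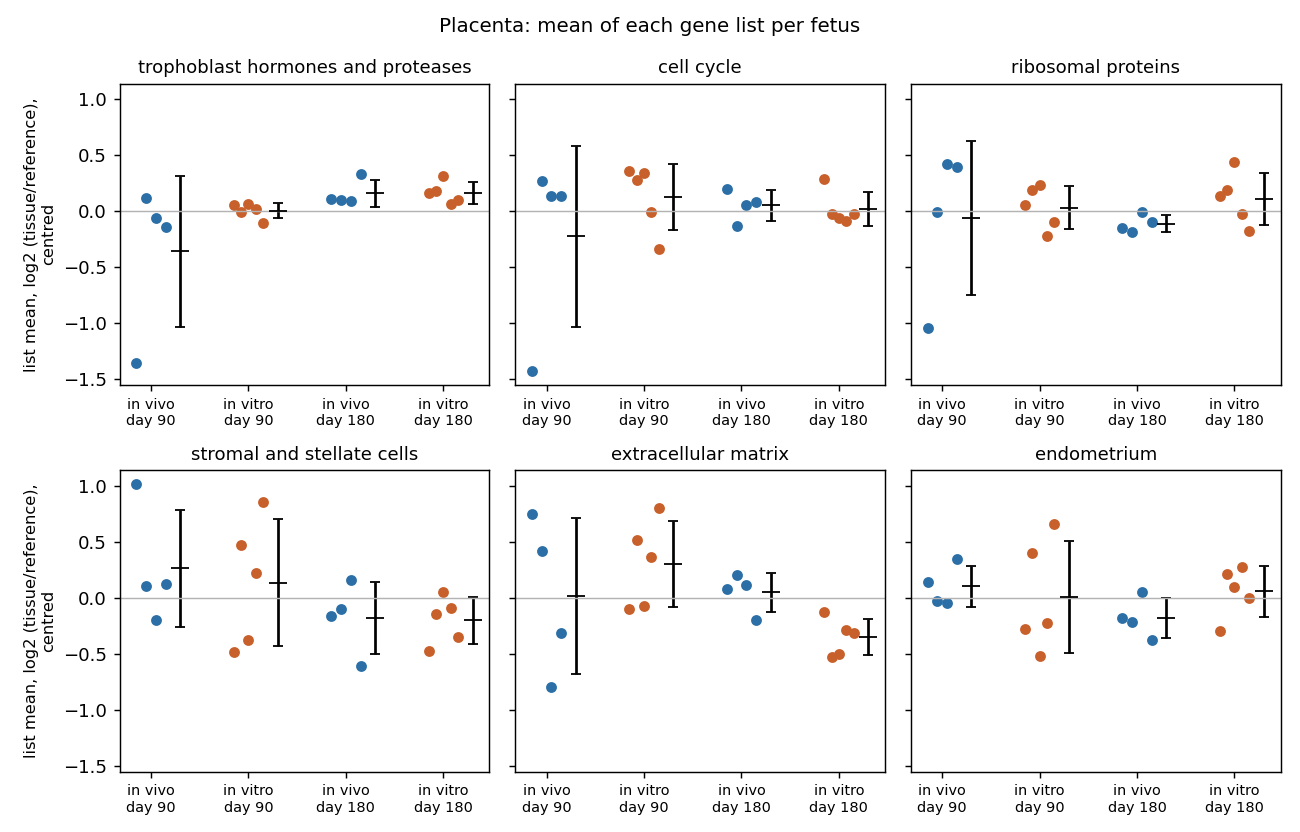
Mean log2(tissue/reference) of 6 gene lists in placenta, with each fetus centred on its own median and each gene on its mean over 18 fetuses. Points are fetuses, and bars are group means with SD (4 in vivo and 5 in vitro fetuses per day). The placenta of in vivo day 90 fetus 1 lies at -1.36 in trophoblast hormones, -1.43 in cell cycle and 1.01 in stromal cells, outside the other 17.

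KCNE2, a subunit of potassium channels, was the only feature that changed between the days in placenta by limma (0.89, SE 0.13, adjusted p 0.0274), with 621 at an unadjusted p under 0.05. It was higher than the day 90 mean in 9 of 9 day 180 fetuses, which its selection made likely. The other genes given by the rule were GGT7 (0.67), EAF2 (0.77), CFAP410 (0.56), MGC139164 (0.88), FADS1 (-0.97, adjusted p 0.137), FADS2 (-0.83, adjusted p 0.137), IGF1 (-1.48, adjusted p 0.146), DKK1 (-0.79) and the microfibril gene MFAP2 (-0.83). The count was 0 with only the first array, 0 with only the second array, and 0 without any of 12 of the 18 fetuses in turn. It was 2 with arrays scaled to the same spread, 18 with fetus and array number as blocks and 44 with array weights.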

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

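The tests of array failure, endometrium and trophoblast share, of the interaction without in vivo day 90 fetus 1, of array spread, of the erythroid share and of liver lists with the transcript score, and the day by tissue comparison, were chosen after the results had been seen. After its result, the transcript length test in liver was read as open, although the count met the bound written for it as a cause, and so were the tests of trophoblast share and endometrium and the splits for counts of 0. The bar for the liver lists with the score was rewritten after their values had been seen: a preset-correlation adjusted p under 0.05, an interval of the mean change without 0 and most of the median kept (the lowest share kept by a list that met it was 71.0%, for erythroid genes; 71.7% for cell cycle).

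The placenta of in vivo day 90 fetus 1 was lower in trophoblast hormone (-1.36), cell cycle (-1.43) and ribosomal protein genes (-1.05) and higher in stromal (1.01) and endothelial genes (0.56) than all other placentas. A single failed array was excluded, since 2 of its 2 arrays lay above the other 34 placenta arrays in stromal minus trophoblast values (2.36 and 2.38 against at most 1.01). Maternal endometrium stays open: 5 other placentas had a higher endometrium list mean than its 0.14 (-0.52 to 0.65 in the others), but the list lay above liver in placenta (median 1.07), and such a baseline could hide a share. A lower share of trophoblast cells may account for it, with 3 of 3 lists outside the others in the needed direction, but 4 of 6 lists of other cell types were above all others and erythroid genes, at -0.01, were exceeded by 10 placentas, so the data leave it open. These list means were centred on each fetus's own median, which was 0.46 here against -0.05 to 0.13 in the others. Without that centring the numbers of placentas above or below it could differ. Degraded RNA stays open, with its short minus long score at -0.95 against -0.29 to 0.75 in the other 17, a placental region with more connective tissue was not tested, and the design names no biological difference between this fetus and its group.

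In placenta, the production differences at day 90 and day 180 ran against each other across genes (r -0.415, rho -0.381; genes are not independent replicates), and 1883 features had an unadjusted p under 0.05 in the interaction, with 662 expected. At that threshold 3 of 100 splits gave as many features, the real split included, which met the bar against chance set in advance. Another split gave 2301, more than the real one, and the split tests were not adjusted for their number. Chance was therefore made less likely but not excluded. The excess did not need in vivo day 90 fetus 1, with 2302 such features without it. Whether these were the same features was not tested, and leaving out a fetus can raise a count by lowering the spread. This fetus was therefore not excluded as a cause for single features or lists. With a short minus long score added, 2561 features had an unadjusted p under 0.05, so the score did not lower the count. A covariate can also raise a count by taking up spread between fetuses. A difference between short and long transcripts, as RNA quality could give, is therefore not excluded. The score took the extracellular matrix median from -0.43 to 0.07, the ribosomal from 0.27 to -0.01 and the endothelial from -0.35 to 0.13, so for these lists it stays open as well. A production effect that differs between the days stays open too, untested beyond these fetuses.

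In liver, 1551 features changed between the days. Only the real split, 1 of 100, gave as many, with 86 in the highest other, which met the bar set in advance. Chance was made unlikely, but 100 splits, unadjusted for the number of split tests, cannot exclude it. Arrays with a wider spread were excluded as the cause, with 1862 changed features after scaling to the same spread. Stromal and hepatocyte lists moved apart (exact permutation p 0.000452, 9 fetuses per day), which a lower share of erythroid cells alone would not give. That argues against this share as the only change if hepatocyte values could rise freely, which was not testable without signal intensities. With the short minus long score added 148 features changed, but the score itself differed between the days (exact permutation p 0.000905) and the median SE grew from 0.176 to 0.239, so transcript length and gestation cannot be told apart for the features that no longer passed. By the bar rewritten after the values were seen, the score did not account for the whole change of 7 lists. Their mean change with the score, against that without it, was 0.67 (SE 0.07) against 0.56 (SE 0.06) for complement, -0.43 (SE 0.08) against -0.65 (SE 0.08) for erythroid and -0.49 (SE 0.10) against -0.67 (SE 0.09) for cell cycle genes. It was -0.11 (SE 0.05) against -0.15 (SE 0.03) for DNA methylation, 0.45 (SE 0.11) against 0.50 (SE 0.08) for matrix, 0.53 (SE 0.14) against 0.70 (SE 0.11) for stromal and -0.20 (SE 0.06) against -0.31 (SE 0.05) for respiratory genes. The score may adjust for transcript length only in part, and a bar set with the values in view cannot weigh against it. Transcript length as their whole cause therefore stays open. With the score, matrix, stromal and respiratory genes lost their call under the stricter test (adjusted p = 0.0989, 0.110 and 0.0778 with an estimated correlation) as SEs grew, though 75.4% of the stromal and 73.0% of the respiratory median were kept and that of matrix went from 0.46 to 0.49. Ribosomal genes did not meet the bar (mean change -0.21, SE 0.08, against -0.30, SE 0.06, with 62.5% of the median kept and adjusted p = 0.130 with an estimated correlation). Transcript length stays open for them too. Gestational age as the biological explanation of the liver changes stays open as well.

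Single samples lay far from the rest of their group in 23 of 344 group tests, with 17 expected by chance. The values are gaps divided by the group's range. In liver they were 0.976 for the spread of in vivo day 180 fetus 4 (1.13), 0.880 for imprinted genes and 0.952 for trophoblast transcription factors in in vivo day 90 fetus 3, 0.876 for trophoblast hormones in in vivo day 90 fetus 4, and 0.742 for cell cycle in in vitro day 180 fetus 2. They were 0.871 for interferon response in in vivo day 180 fetus 2, 0.740 for myeloid genes in in vitro day 90 fetus 4, 0.750 for stromal genes in in vitro day 90 fetus 5 and 0.715 for APOA1 in in vitro day 180 fetus 4.

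In placenta, in vivo day 90 fetus 1 had 0.914 for its median, 0.908 for fatty acid oxidation, 0.947 for antioxidant defence, 0.920 for cell cycle, 0.949 for oxidative phosphorylation, 0.856 for muscle genes and 0.881 for PAG2. For in vitro day 180 fetus 1 the values were 0.780 for heat shock, 0.819 for cell cycle and 0.747 for megakaryocyte genes. The others were 0.971 for the correlation between both arrays of in vivo day 180 fetus 1 (r 0.838), 0.723 for hepatocyte genes in in vitro day 90 fetus 1, 0.858 for fatty acid synthesis in in vivo day 180 fetus 3 and 0.930 for trophoblast hormones in in vivo day 180 fetus 4.

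Effects also differed between groups by a test of the difference itself. The liver production by day interaction had cell cycle genes (adjusted p 0.00018). That of placenta had 1 changed feature, cholesterol synthesis (0.00338), extracellular matrix (4.7e-05), heat shock (0.00338), cell cycle (0.0164) and endothelial genes (0.0164). The production by tissue interaction had glycolysis (0.0490), fatty acid synthesis (0.0135), oxidative phosphorylation (8.38e-08) and ribosomal proteins (0.000473). The day by tissue interaction had 275 changed features and 17 lists. With an estimated correlation, only the erythroid list of the day by tissue interaction kept its call among all of these.

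The other counts were set beside splits into groups of the same sizes. A count of 0 is reached by any split (100 of 100), so for the production contrasts with 0 changed features the splits decide nothing. The highest other was 1757 in liver with days averaged, 1 at day 90, 552 at day 180 and 2847 in the interaction, and in placenta 12 with days averaged, 209 at day 90, 49 at day 180 and 22 in the production by tissue interaction. Within a tissue, 1 to 5 of 99 other splits gave any call. Splits with so many features may reflect a structure of the samples: in liver, the arrays of the groups differed in spread by 0.196 in the highest split with days averaged against 0.00916 in the real one, by 0.211 against 0.0568 at day 180 and by -0.383 against 0.0953 in the interaction. In placenta at day 90 the spread difference was -0.0540 in the highest split against -0.0704 in the real one, so spread does not account for that split. The single feature of the placenta interaction was reached by 2 of 100 splits (highest other 1). Chance was not excluded for it, since the count was 0 without any of 11 of 18 fetuses in turn, with median centring, with quantile normalization and with either array alone. KCNE2 in the placenta day contrast was reached by 5 of 100 (highest other 1758), so chance was not excluded. The 8337 features of placenta minus liver met the bar against chance set in advance (1 of 100, highest other 1189), which made chance unlikely. For the 275 of day by tissue 2 of 100 splits gave as many, but another gave 539, so chance was less likely but not excluded. With array weights, chance was not excluded for the 1664 features of placenta at day 90 (6 of 100, highest other 2307), nor for the 3220 of the interaction (2 of 100, highest other 3315).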

How the results depend on the processing

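Scaling to the same spread, array weights, tests on named features and list tests without a fetus were chosen after the results had been seen, as was the day by tissue comparison under all alternatives. Apart from fits without a fetus, 126 counts stayed within 1.5 times the reported one, 13 were higher and 36 lower. The 126 include counts of 0 that stayed 0, which say little about stability. Of 21706 alternative values for the genes named, 0 reversed a call, 442 lost it, 250 gained it and 26 moved. Of the genes named that passed, 70 of 108 passed under every alternative for liver by day, 145 of 149 for placenta minus liver and 21 of 52 for day by tissue. Of 92 list calls, 1 median changed sign under a scaling. Unless a construction is named, the cause was not tested.

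Fewer arrays gave fewer features: only the first array gave 536 for liver by day, 0 for the placenta interaction, 0 for placenta by day and 82 for day by tissue, and only the second 0 for the placenta interaction and 0 for placenta by day. Median centring and quantile normalization each gave 0 for the placenta interaction. Scaling to the same spread gave 2 for placenta by day and 178 for day by tissue. Tests on named features, fewer by construction, gave 1009 for liver by day, 5515 for placenta minus liver and 0 for the placenta interaction. The fit with fetus and array number as blocks gave 1 for placenta production with days averaged, 99 for the placenta interaction and 18 for placenta by day; the arrays of a fetus correlated with 0.435 in liver and 0.439 in placenta. Unpaired fits without the fetus block gave 8476 for placenta minus liver and 383 for day by tissue.

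Array weights gave 1 for liver production at day 90, 2437 for liver by day, 1 for placenta production with days averaged, 1664 at day 90, 57 at day 180, 3220 for the placenta interaction, 44 for placenta by day and 1 for production by tissue. In vivo day 90 placentas had weights of 0.116, 0.450, 1.11 and 6.09, so the last had most of the weight of its group in the placenta fits.

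Lists called with an estimated correlation numbered 1 for liver production with days averaged, 0 at day 90, 0 at day 180 and 0 in its interaction, 8 for liver by day, 0 in each of the 5 placenta contrasts, 7 for placenta minus liver, 0 for production by tissue and 1 for day by tissue. Fry, which compares lists with no other genes, called 0 in each of the production contrasts and placenta by day, 26 for placenta minus liver and 10 for day by tissue.

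The share of higher features fell from 56.0% to 38.3% with median centring, 40.9% with quantile normalization, 43.3% with the first array and 45.3% with named features for liver by day. For day by tissue it grew from 24.7% to 44.9% with median centring and 43.2% with quantile normalization.

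Leaving out each fetus gave 0 to 0 features for the liver production contrasts, 985 (without in vivo day 90 fetus 1) to 2165 (without in vitro day 90 fetus 5) for liver by day, 0 to 1 for placenta production with days averaged, 0 to 13 at day 90, 0 to 1 at day 180, 0 to 328 in the interaction, 0 to 2 for placenta by day, 7973 to 8540 for placenta minus liver, 0 to 1 for production by tissue and 136 to 394 for day by tissue. Lists called ranged from 2 to 3, 0 to 2, 0 to 5 and 0 to 3 for liver production (averaged, day 90, day 180, interaction), 17 to 19 for liver by day, 2 to 8, 5 to 9, 4 to 7 and 4 to 8 for the same placenta contrasts, 6 to 12 for placenta by day, 15 to 18 for placenta minus liver, 2 to 10 for production by tissue and 14 to 18 for day by tissue. Without signal intensities, the limit set by signal over background is unknown.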

Other observations

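The day by tissue comparison and the correlation tests here were chosen after the results had been seen. Growth factor and complement genes changed differently with gestation in placenta than in liver. IGF1 rose in liver (1.38) and differed by -1.48 in placenta, and the difference between the tissues was -2.85 (SE 0.30, adjusted p 4.92e-05). IGFBP2, which binds the same growth factor, had a difference of -2.82, the complement genes C1R, C1S and C3 -3.68 (SE 0.53), -3.02 and -2.52, the T cell chemokine CXCL9 -3.28, the collagen gene COL1A2 -2.86, SFRP2, a modulator of WNT signals, -2.60 and MATN2, SCARA5, HSD17B6 and DPT -2.43 to -2.28. On the other side stood the calcium-binding protein gene S100G (1.82), EAF2 (1.64), the polyamine oxidase SMOX (1.57), the mitotic genes KIF15, NCAPG and CENPE (1.502, 1.33 and 1.28), the platelet factor PF4 (1.49), the transferrin receptor TFRC (1.49), the serine synthesis enzyme PSPH (1.43), the glucose transporter SLC2A1 (1.41), ALAS2 (1.40) and ORM1 (1.37). By limma the day change of 275 features differed between the tissues, higher in placenta than in liver for 68 and lower for 207. Higher and lower compare day changes in this contrast, not expression levels. Of the 24 genes named here, chosen for their large differences, 21 had their direction in 9 of 9 day 180 fetuses. The share of higher features was 24.7% as deposited, 44.9% with median-centred and 43.2% with quantile-normalised arrays, so the excess of lower features rested in large part on the scaling. The count was 161 without in vivo day 90 fetus 1, 153 without in vitro day 90 fetus 2, 142 and 136 without in vivo day 180 fetuses 1 and 4, and 167 and 172 without in vitro day 180 fetuses 1 and 4, and it was 82 with only the first array and 178 with arrays scaled to the same spread. The median of all features was -0.13 in this contrast.

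The erythroid list was the only one that kept camera's call with an estimated correlation (adjusted p = 0.00112, and 1.36e-09 at the preset correlation). Of its 15 genes 5 were higher and CA2 lower (11 and 2 adjusted over the list alone), with a median of 0.85. Of 46 cell cycle genes 2 were higher (27 adjusted over the list alone; median 0.72), among them CDK2 (0.74). Matrix genes were lower in 8 of 45 (23 adjusted over the list alone; median -0.71), stromal markers in 5 of 14 (9 adjusted over the list alone; median -1.15), myeloid markers in 8 of 26 (16 adjusted over the list alone; median -0.81), lymphoid markers in 3 of 19 (9 adjusted over the list alone; median -0.74), interferon response genes in 3 of 27 (9 adjusted over the list alone; median -0.62) and complement and coagulation genes in 5 of 22 (6 adjusted over the list alone; median -0.51). Camera called these and 9 other lists, and for all except the erythroid list adjusted p = 0.133 to 0.279 with an estimated correlation. The others were IGF and insulin axis and drug metabolism (lower), and glycolysis, cholesterol synthesis, DNA methylation, nutrient transport, antioxidant defence, oxidative phosphorylation and ribosomal proteins (higher). Without in vivo day 90 fetus 1, 14 of the 17 calls remained, and glycolysis (0.132), cholesterol synthesis (0.0839) and antioxidant defence (0.0839) did not. Glycolysis was not called without in vitro day 90 fetus 5 (0.0903) or in vitro day 180 fetus 3 (0.0828) either. The ribosomal median was 0.28 with and 0.17 without in vivo day 90 fetus 1.

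Cell cycle transcripts in fetal liver may come with the erythroid cells, which divide there in the fetus. Within day 90, the list means correlated over 9 fetuses (r 0.960, exact permutation p 0.000209, adjusted 0.000419; rho 0.933, p 0.00075), and r was 0.899 without the 2 fetuses farthest from the median. Within day 180 r was 0.761 (exact permutation p 0.0183, adjusted 0.0183; rho 0.35, p 0.359), but -0.137 without 2 fetuses, so there the relation rests on those. These 2 correlations were the whole family, and the hypothesis stays open.

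Across genes, which are not independent replicates, the production difference in liver at day 90 had an r of 0.0166 with that at day 180, and the production differences of liver and placenta had 0.00535. The gestational differences of both tissues had an r of -0.0727.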
